A study of Rattus norvegicus and Mus musculus with 4 samples.

How the data were processed

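Total RNA was extracted from cultured cells with a column kit, labelled with biotin and hybridised to Affymetrix expression arrays, per the labels. The 4 samples form 4 groups of 1 array, McA-RH7777 cells and mouse microvessel endothelial cells, each 36 h after rAAV-HGFK1 or rAAV-EGFP; groups were taken from the source names in the labels. The deposited values are intensities, 1 signal per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version and settings of MAS5 are not given in the sources used here. The 2% trimmed mean of all probe sets was 500.2 on both rat arrays and 500.0 on both mouse arrays, so the deposited intensities were used as they stood; had the trimmed means of a pair differed by over 5%, they would have been rescaled. Such scaling sets the average signal of every array equal, and a change shared by most transcripts would not be seen. The submitters' series text calls probe sets at least 2-fold apart differentially expressed, and that threshold was kept. The pathway software the series text names was not used here.

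Control probe sets (57 on the rat and 64 on the mouse array) were left out of the comparisons. Signals under the median of all remaining signals of a pair (69.8 in McA-RH7777 cells, 52.9 in the endothelial cells) were set to that median, called the floor. A probe set was measured if at least 1 of its 2 signals was above the floor, and its log2 fold was the log2 of the HGFK1 signal over the EGFP signal. A fold with 1 signal at the floor is a lower bound and is written as at least that fold. Detection calls were not used here. Gene symbols came from the platform annotation given with the arrays and were compared with a current rat gene table through Entrez identifiers. Of 31042 rat probe sets used, 20826 had 1 symbol, 436 several and 9780 none; of 45037 mouse probe sets, 34945, 932 and 9160. Of the rat probe sets with 1 symbol, 20758 matched the current table and in 0 of them the symbol differed; mouse symbols were used as given. Probe sets with several symbols named no gene. A gene took the value of its measured probe set with the highest mean log2 signal. Where another measured probe set of a named gene had the opposite sign, its value is given unless it rounds to 0.00.

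Before the data were examined, 49 gene lists were fixed from general knowledge, on HGF, EGF receptor and other signalling, angiogenesis, cell type markers, cell cycle, apoptosis, stress, metabolism, matrix and translation. For each list with at least 5 measured members, the median log2 fold was set against the medians of 10000 random lists of the same size drawn from 10 bins of mean signal. A list stands apart where its percentile was at most 2.5 or at least 97.5. These percentiles describe the 2 arrays of a pair and test nothing about the treatment. List names absent from an array were also looked up as synonyms in the rat gene table, and 10 synonyms that led to a different or unclear gene were left out by hand. Both steps were added after list medians had first been seen and were made on names alone; medians without synonyms were computed as an added alternative.

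The rule for named genes was also fixed before the data were examined. It took, per cell type, the 8 highest and 8 lowest genes with both signals above the floor, a fold of at least 2, 1 symbol and no other measured probe set of opposite sign, passing over predicted loci. It took the 4 members furthest in the direction of the median for each list that stood apart, and the 2 members furthest from 0 for other lists described. Hgf, Met and Egfr were always named, and up to 6 genes at least 2-fold apart in both cell types in the same or in opposite directions, of which there were 0. Afp, Pecam1, Cd34, Kdr, Flt1, Tek and a few genes marked as chosen after their values were seen stand outside this rule, and 1 gene that it took in the endothelial cells is not reported here. Rat and mouse genes were paired by identical symbols.

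No test across samples was possible with 1 array per group. The procedure was tested on simulated data for each pair. In McA-RH7777 cells, 99 of 100 probe sets simulated at 3-fold and 100 of 100 at 6-fold were found, with 83 of 30842 unchanged probe sets at least 2-fold apart. In the endothelial cells the numbers were 100 of 100, 100 of 100, and 690 of 44837. The changed probe sets were simulated only where the mean log2 signal was over 1.5 above that of the floor. Probe sets at least 2-fold apart in the data had lower median signals, 153 and 93.6, so recovery at the signals of most of them was not tested. The simulated spread at each signal was taken from the same pair and holds any response to the vector, so these counts do not estimate how many probe sets would be 2-fold apart with no response. Among 200 unshifted simulated lists, 4 and 13 lay outside the middle 95% of random lists. Alternatives fixed in advance were median centring, quantile normalization, removal of a loess curve (span 0.3), floors at the 25th and 75th percentile, no floor, a pseudocount of the median signal, thresholds of 3-fold and 1.5-fold, counting genes, averaging probe sets of a gene, and leaving out probe sets shared between transcripts by design. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.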

Results

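RNA from a rat liver tumour line and from mouse endothelial cells was measured 36 h after treatment with 1 of 2 recombinant adeno-associated virus vectors (rAAV). One vector, rAAV-HGFK1, is named for kringle 1, a folded domain of hepatocyte growth factor (HGF), which signals through the receptor Met. The other, rAAV-EGFP, is named for a green fluorescent protein and was the submitters' baseline. McA-RH7777 is a rat hepatocellular carcinoma line, and the endothelial cells came from microvessels of mice. The series title names anti-angiogenic and anti-tumour signalling as its subject, so the question was which transcripts differed between the vectors in each cell type. Each of the 4 groups was 1 array, with 31099 probe sets on each rat array and 45101 on each mouse array. No comparison therefore has replicates or a replicate check, no p-value across genes is given, and higher or lower below means higher or lower on the HGFK1 array than on the EGFP array of that cell type. The number of arrays limits the precision of every value.

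Most transcripts that mark each cell type were measured, with at least 1 signal of the pair above the floor. In McA-RH7777 cells 22 of the 24 hepatocyte markers on the array were measured, and the fetal liver protein Afp had signals of 30501 with HGFK1 and 27784 with EGFP. Only 2 of 21 endothelial markers, Egfl7 and Esam, were measured there. In the microvessel endothelial cells 21 of 24 endothelial markers were measured, among them Pecam1 at 11373 and 10782 and Cd34 at 15178 and 13781. Their median log2 fold was 0.01, at the 55.6th percentile of random lists, and the list ran from -0.27 for Esam to 0.67 for Mmrn2. Of markers of other cell types, 5 of 16 fibroblast, 6 of 12 smooth muscle, 8 of 17 leukocyte and 5 of 12 epithelial genes were measured in the endothelial cells. So were 7 of 24 hepatocyte markers and 4 of 7 cholangiocyte and progenitor markers, too few of the latter to rank. No median of the ranked lists lay outside the middle 95% of random lists. With so few genes that range was wide, from -0.22 to 0.23 for leukocyte and from -0.50 to 0.57 for epithelial genes, so smaller shifts would not show.

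Few transcripts of McA-RH7777 cells differed at least 2-fold, and most of those were higher with HGFK1. Ubn2, a ubinuclein, was 3.57-fold higher (signals of 321 with HGFK1 and 90.0 with EGFP), and Mga, a partner of the transcription factor Max, was 2.92-fold higher. The chromatin or DNA-binding genes Arid4a at 2.43-fold, Ankrd11 at 2.37-fold and Arid5b at 2.36-fold followed, with the vesicle glycoprotein Sv2b at 2.32-fold, the calcium-dependent lipid-binding protein Cpne3 at 2.29-fold and the SMN complex member Gemin5 at 2.25-fold. Lower with HGFK1 were Pias1, a SUMO ligase, by 2.51-fold (signals of 421 and 1056), the mitochondrial ubiquitin ligase Mul1 by 2.41-fold, the actin-oxidising enzyme Mical2 by 2.32-fold and the endosomal protein Zfyve16 by 2.30-fold. Id4, an inhibitor of helix-loop-helix transcription factors, was 2.22-fold lower, the Integrator subunit Ints3 2.15-fold, the zinc finger gene Zfp874b 2.14-fold and the phospholipase Plcb3 2.09-fold. Of 16181 measured probe sets, 137 were at least 2-fold higher and 26 at least 2-fold lower, together 1.01%. Counted by the brightest probe set of each of 9379 genes, 30 genes were higher and 14 lower. Other probe sets of Mga and Mical2 had log2 folds of 0.01 and -0.01, those of Ankrd11 0.67 and 0.10, and those of Gemin5, Id4 and Pias1 0.46, -0.37 and -0.22, and 5 of the 8 genes named as higher and 5 of the 8 named as lower had a single measured probe set. The counts moved with the floor on low signals: with a floor at the 75th percentile of signals 19 probe sets were higher and 2 lower, and with no floor 4205 were higher and 2571 lower. Some probe sets outside the naming rule lay further apart than the genes named, among them those of Acbd3 at a log2 fold of 2.43, Srrm1 at 2.37 and Lpgat1 at -1.35, while the brightest probe sets of these genes gave -0.12, 0.04 and 0.71.

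**Figure D1:**
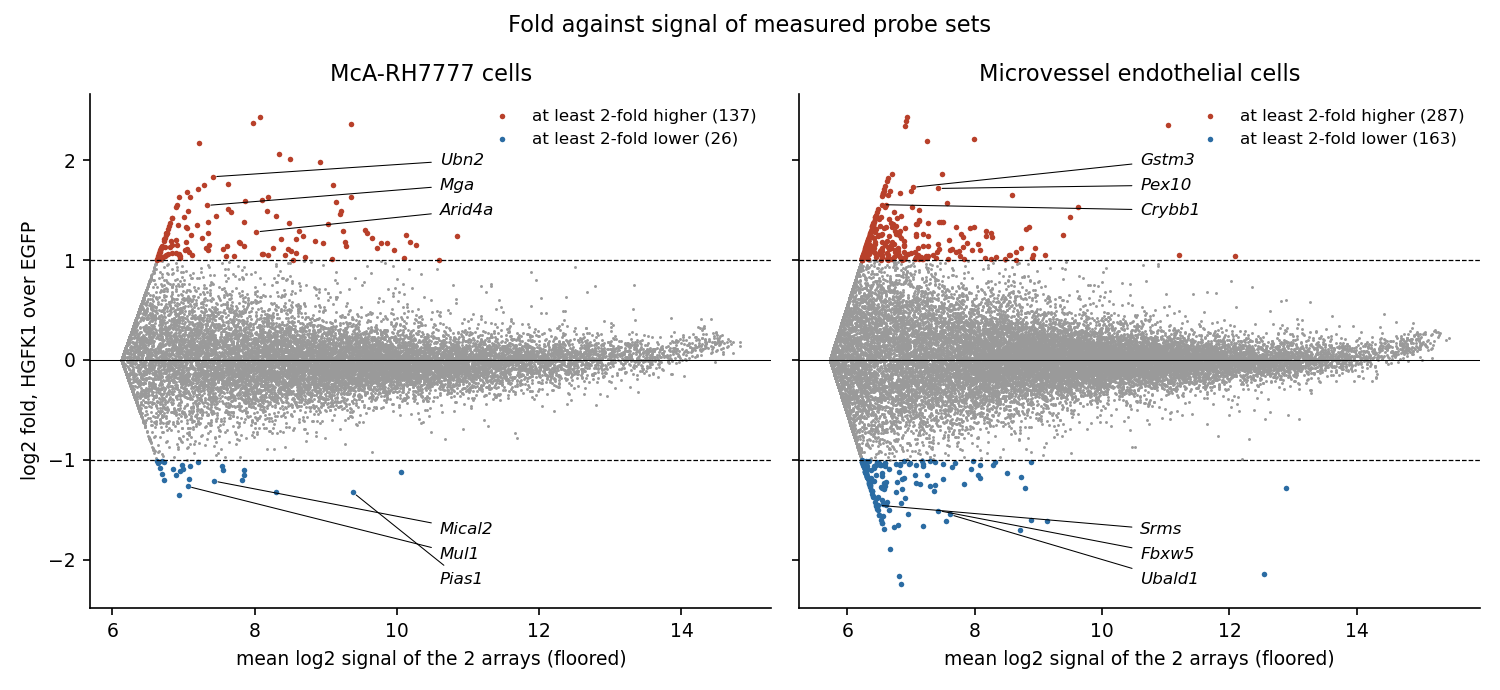
Log2 fold (HGFK1 over EGFP) of each measured probe set against its mean log2 signal over the 2 arrays, after signals below the floor were set to it, in McA-RH7777 cells (left) and microvessel endothelial cells (right). Dashed lines mark 2-fold; red points (137 left, 287 right) are at least 2-fold higher and blue points (26 left, 163 right) at least 2-fold lower, 3 of the highest and 3 of the lowest named genes of each cell type are labelled, and most coloured points lie at low signals.

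Gene groups in McA-RH7777 cells shifted by far less than 2-fold. Hepatocyte markers were slightly higher with HGFK1, with 20 of 22 members above 0 and a median log2 fold of 0.15, at the 99.98th percentile of 10000 random lists matched on signal. The median was 0.08 after quantile normalization and 0.09 after removal of a loess curve, where the list still stood apart. Among them were the cytochrome Cyp2e1 at 0.44, the thyroid hormone carrier Ttr at 0.41 and the apolipoprotein Apoa2 at 0.38, while Pck1, of gluconeogenesis, was at least 1.31-fold higher with its EGFP signal under the floor. Targets of transforming growth factor beta (TGF-beta) were lower, with 11 of 14 members below 0 and a median of -0.22 (0.05th percentile). They included the TGF-beta feedback genes Skil at -0.35 and Tgif1 at -0.34 and the receptor Tgfbr1 at -0.32, and Tgfb3 was at least 1.19-fold lower with its HGFK1 signal under the floor, while the member furthest from 0 was Tgfbi, which was higher at 0.37. With no floor and with a pseudocount in its place, the TGF-beta list lay within the middle 95% of random lists.

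Genes of the G1/S transition were higher in McA-RH7777 cells, with 14 of 18 members above 0 and a median of 0.12 (99.6th percentile). Cyclin Ccnd3 was at 0.59, the kinase Cdk6 at 0.57, the phosphatase Cdc25a at 0.50 and the thymidine kinase Tk1 at 0.26, although another probe set of Tk1 gave -0.12. The lowest member was the cyclin Ccne2 at -0.55, with another probe set at 0.46. With a floor at the 75th percentile of signals this list lay inside the range of random lists (96.5th percentile). The opposing list of cyclin-dependent kinase inhibitors and growth arrest genes was also higher, with 10 of 14 members above 0 and a median of 0.12 (98.6th percentile). Gas6, with its EGFP signal under the floor, was at least 1.27-fold higher and was followed by Cdkn2a at 0.20, Gadd45b at 0.19 and Cdkn1a at 0.15, while the member furthest from 0 was Cdkn2b at -0.48. Genes of DNA replication, with a median of -0.04, and of mitosis, at 0.05 (96.8th percentile), lay within the range of random lists. Unfolded protein response genes were lower, with 15 of 25 members below 0 and a median of -0.07 (0.57th percentile), among them the oxidoreductase Ero1b at -0.50, the chaperone Hyou1 at -0.34, Edem1 at -0.34 and the transcription factor Ddit3 at -0.28. Other probe sets of Cdkn1a, Gas6 and Edem1 gave -0.09, -0.17 and 0.28. The growth arrest and unfolded protein response lists lay inside the range of random lists when all probe sets of a gene were averaged, at the 81.5th and 12.9th percentiles, and the growth arrest list also did with a lower floor, no floor or a pseudocount. Cytosolic ribosomal protein genes had a median of 0.16, above all random lists, with 27 of 31 members above 0, but a median of -0.01 after quantile normalization and of 0.07 after removal of a loess curve. Rplp0 was at 0.32, Rps24 at 0.25, with another probe set at -0.03, Rps9 at 0.23 and Rpl30, at low signal, at 0.42. In all, 6 of 42 ranked lists lay outside the middle 95% of random lists, and 5% of 42 lists is 2.1. That value holds for lists of unrelated genes, and some lists here share members, so it does not measure an excess.

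In the microvessel endothelial cells, most probe sets at least 2-fold apart were again of low signal. Of the genes taken by the naming rule, the glutathione transferase Gstm3 was 3.32-fold higher with HGFK1 (signals of 237 and 71.6), the peroxisome assembly gene Pex10 3.29-fold and the lens crystallin Crybb1 2.94-fold. Odf2l was 2.83-fold higher, the Golgi protein Paqr3 2.71-fold, the microtubule-associated protein Eml1 2.68-fold, the zinc finger gene Zfp420 2.64-fold and Pnmt, which makes adrenaline, 2.57-fold. Lower with HGFK1 were Ubald1 by 2.92-fold (signals of 114 and 334), the F-box gene Fbxw5 by 2.85-fold and the tyrosine kinase Srms by 2.74-fold. Acap3, a regulator of ARF GTPases, was 2.70-fold lower, the amidase Naaa 2.68-fold, the peptidase Lmln 2.62-fold and the sulfotransferase Ust 2.59-fold. The lower signals of Crybb1, Srms, Lmln and Ust, at 54.6, 54.1, 54.9 and 55.6, lay just above the floor of 52.9. Of 24501 measured probe sets, 287 were at least 2-fold higher and 163 at least 2-fold lower, together 1.84%. By brightest probe set, 79 of 12159 genes were higher and 59 lower. A single measured probe set stood behind 6 of the 8 genes taken by the naming rule as higher and all 8 taken as lower. With a floor at the 75th percentile of signals 6 probe sets were higher and 4 lower, and with no floor 6585 and 6074. Some probe sets outside the naming rule lay further apart than the genes named, among them those of Nrxn3 and Psma6 at log2 folds of 2.43 and 2.39, both bounds, and of Nme1 at -2.14. Other probe sets of Psma6 gave 0.17 and -0.13, and that of Nme1 gave 0.06.

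The HGF and Met signalling list was higher in the endothelial cells, with 14 of 17 members above 0 and a median log2 fold of 0.11 (98.0th percentile). The regulatory subunit Pik3r1 of phosphoinositide 3-kinase was at 0.94, the kinase Src at 0.79, with another probe set at -0.30, the receptor Mst1r at 0.30 and Met itself at 0.28 (signals of 1020 and 837). In McA-RH7777 cells the same list had a median of 0.00 (65.7th percentile), and Met was at 0.15. In that list Stat3 was 2.38-fold higher in McA-RH7777 cells by 1 probe set (1722 and 723), and its other measured probe set gave -0.36, while Rapgef1 was at -0.82. The only measured Hgf probe set was in the endothelial cells, at 63.4 with HGFK1 and under the floor with EGFP, at least 1.20-fold higher. Whether Hgf probe sets cover kringle 1 is not given in the sources used here, so they do not check the vector. The list left the tail of the random lists in the endothelial cells when all probe sets of a gene were averaged (95.9th percentile), when probe sets shared between transcripts were left out (94.2nd percentile), with a floor at the 25th percentile and with no floor.

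G1/S genes were slightly lower in the endothelial cells, with 13 of 22 members below 0 and a median of -0.10 (0.44th percentile). The thymidylate synthase Tyms was at -0.35, the retinoblastoma relative Rbl1 at -0.33 and the transcription factors E2f3 and E2f1 at -0.32 and -0.31, with other probe sets of Rbl1, E2f3 and E2f1 at 0.14, 0.17 and 0.30. The member furthest from 0 was E2f2, which was higher at 0.88. Averaging probe sets brought this list to -0.05 (8.2nd percentile). Oxidative stress genes under the transcription factor NRF2 had a median of 0.06 (97.8th percentile), with the glutathione synthesis gene Gclc at 0.40, the haem oxygenase Hmox1 at 0.36, Akr1b8 at 0.17 and Sod1 at 0.15, and lay at the 55.1st percentile after quantile normalization. They also lay inside the range of random lists with loess, a floor at the 25th percentile or a pseudocount. The same list had a median of 0.08 (96.6th percentile) in McA-RH7777 cells, inside that range. Ribosomal protein genes had a median of 0.15, above all random lists, with 32 of 34 members above 0, and a median of -0.01 after quantile normalization and of 0.10 after loess. Rps27 was at 0.74, Rpl12 at 0.68, Rpl6 at 0.28 and Rplp0 at 0.26. In all, 4 of 46 ranked lists lay outside the middle 95% of random lists, and 5% of 46 lists is 2.3, which again does not measure an excess.

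**Figure D2:**
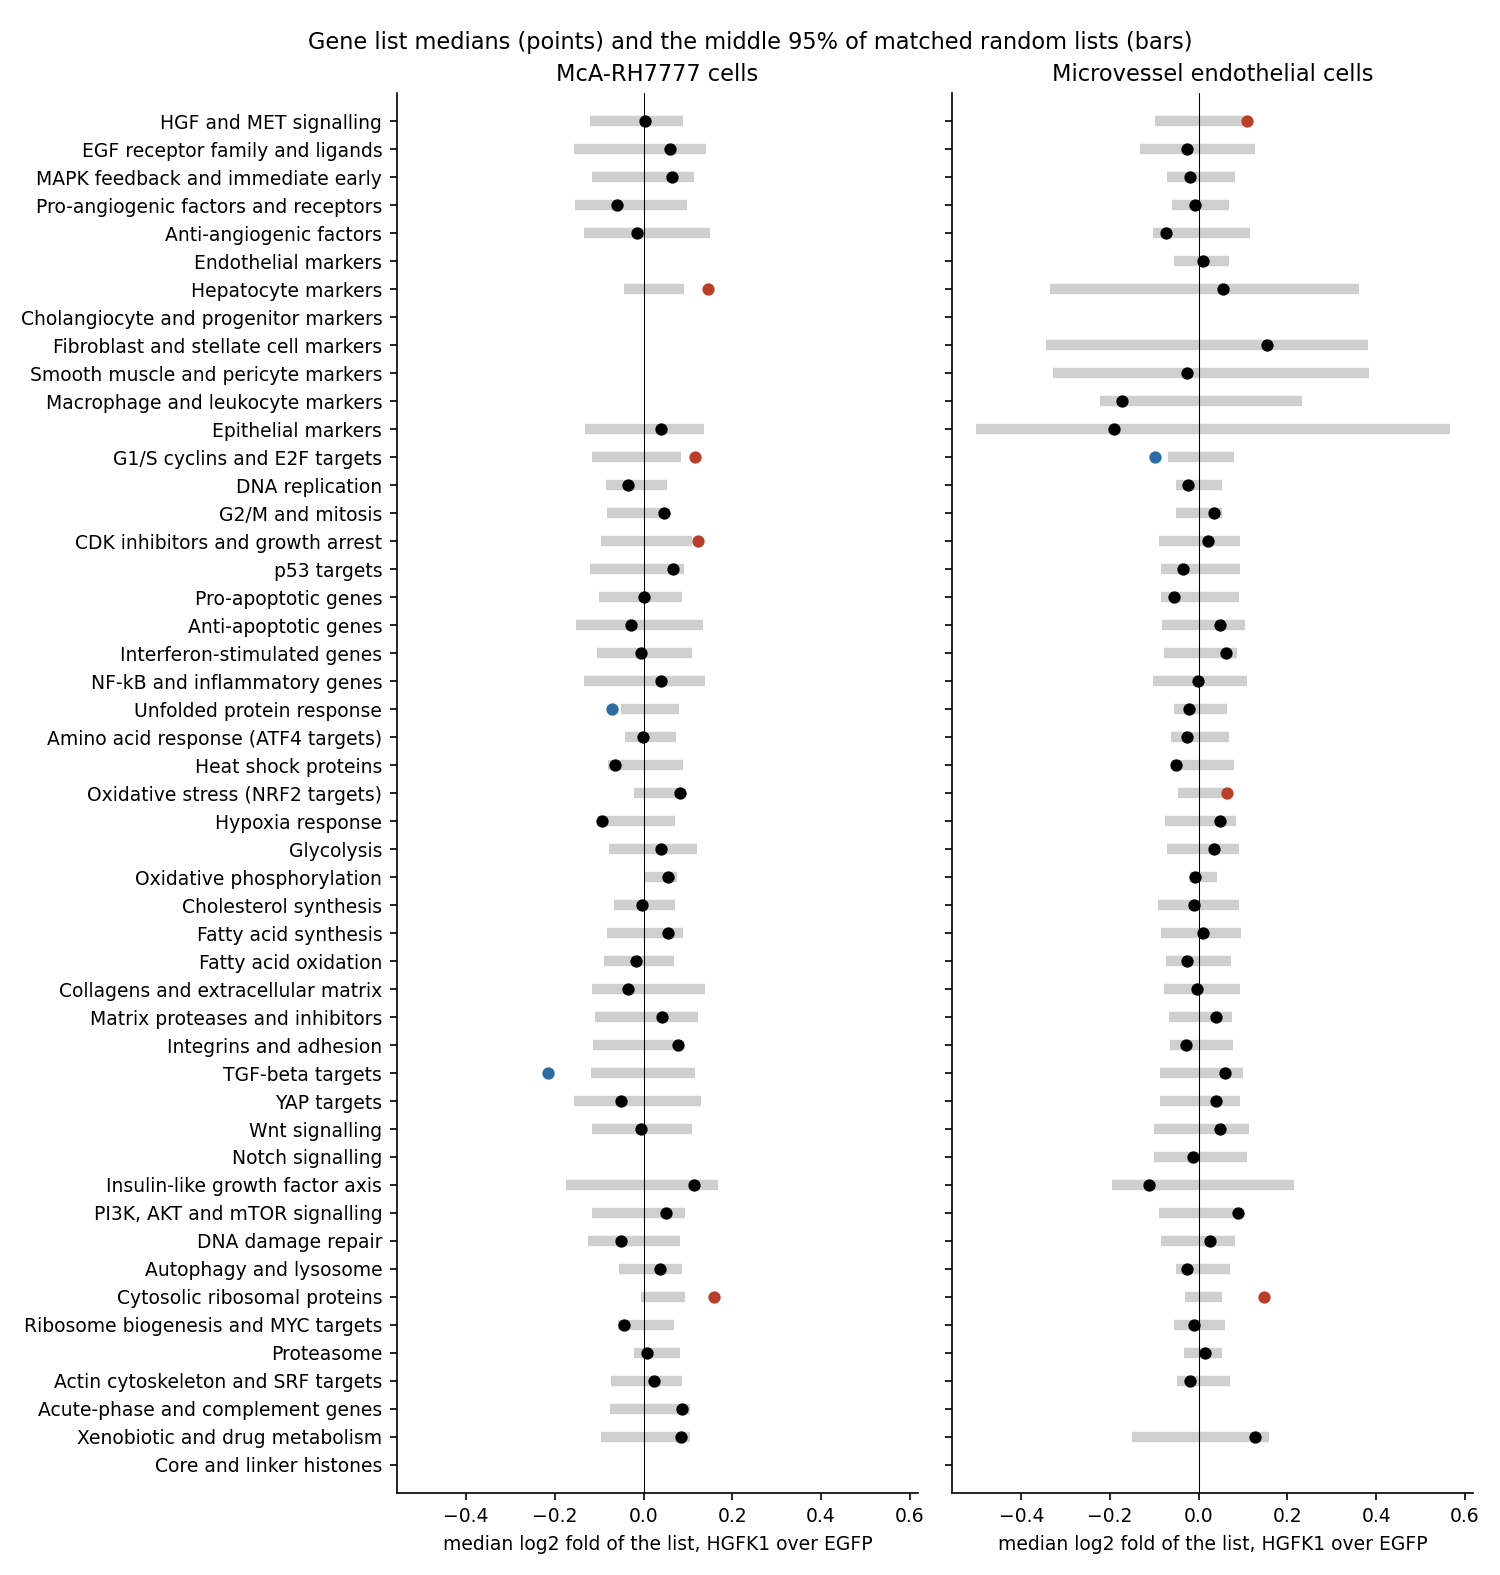
Median log2 fold (HGFK1 over EGFP) of the measured members of each gene list (points) and the middle 95% of medians of 10000 random lists matched on signal (grey bars), in McA-RH7777 cells (left) and microvessel endothelial cells (right); lists with fewer than 5 measured members have no point. Red points lie above and blue points below the bars, 6 of 42 lists on the left and 4 of 46 on the right; the ribosomal protein medians of 0.16 and 0.15 became -0.01 and -0.01 after quantile normalization.

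Lists for angiogenesis, the epidermal growth factor (EGF) receptor and apoptosis did not stand apart in either cell type. In the endothelial cells the pro-angiogenic factors and receptors had a median of -0.01 (37.1st percentile), with the VEGF receptors Kdr at 0.02 and Flt1 at -0.01 (other probe sets from -0.05 to 0.03) and the angiopoietin receptor Tek at -0.08. The outermost members were Pdgfra at 0.72 and Vegfd, under the floor with HGFK1, at least 1.43-fold lower. Anti-angiogenic factors had a median of -0.07 (7.93rd percentile) in the endothelial cells, with Col18a1, the source of endostatin, at 0.62 and Spry2 at 0.39, and -0.01 (35.2nd percentile) in McA-RH7777 cells, where the protease inhibitor Timp2 was at -0.80 and the chemokine Cxcl9 at -0.30. Pro-angiogenic genes in McA-RH7777 cells had a median of -0.06 (29.4th percentile), with 10 of 13 members below 0, Pdgfa at 0.58 and Ephb4 at -0.18. Egfr was at 0.05 in McA-RH7777 cells (signals of 2213 and 2134), where its other probe sets gave 0.17 and, with its HGFK1 signal under the floor, -0.41. The endothelial value of Egfr was 0.59 (169 and 112), and its other measured probe sets gave 0.34 and, also with its HGFK1 signal under the floor, -0.25. The remaining Egfr probe sets were under the floor on both endothelial arrays, with signals from 1.24 to 41.6. EGF receptor family medians were 0.06 (82.3rd percentile) and -0.03 (37.0th percentile) in the 2 cell types, with Erbb2 at 0.26 and Adam10 at -0.24 in McA-RH7777 cells and the ligand Nrg1 at -0.69 in the endothelial cells. Pro-apoptotic genes had a median of 0.00 (56.1st percentile) in McA-RH7777 cells, from Hrk at -0.56 to Endog at 0.61, and of -0.06 (9.41st percentile) in the endothelial cells, where 19 of 25 members were below 0, Diablo was at -0.42 and Fas, under the floor with HGFK1, at a bound of -0.57. Anti-apoptotic medians were -0.03 (35.9th percentile) and 0.05 (80.6th percentile), with Bcl3 at -0.94 and Xiap at 0.41 in McA-RH7777 cells and Cflar at 0.27 and Birc6 at 0.23 in the endothelial cells. Other probe sets of Col18a1, Cflar, Diablo and Birc6 gave -0.25, -0.89, 0.05 and -0.02 there.

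Across all lists, 3 of 802 measured member genes differed at least 2-fold in McA-RH7777 cells and 3 of 924 in the endothelial cells. In McA-RH7777 cells they were Stat3, the Wnt co-receptor Lrp6, 2.05-fold higher, and the integrin Itga1, at least 2.02-fold higher. In the endothelial cells they were the tropomyosin Tpm2 at -1.17, the integrin Itgb7 at -1.12 and the stress gene Sesn2 at -1.69, all with the HGFK1 signal under the floor, so that these log2 folds are bounds. A second probe set of Sesn2 gave 0.63. Over all genes by brightest probe set, 30 of 9379 were at least 2-fold higher and 14 lower in McA-RH7777 cells. In the endothelial cells 79 of 12159 were higher and 59 lower, so changes of this size were few outside the lists too.

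The folds of single genes were not correlated between the 2 cell types. Over 7889 genes paired by symbol and measured in both, the log2 folds had a Pearson correlation of 0.00 and a Spearman correlation of 0.00 across genes, which are not independent replicates. The same direction was seen for 50.8% of genes. No gene was at least 2-fold higher in both, lower in both or apart in opposite directions, where independent lists would share at most 0.105 genes in any of these combinations. Outside the rule for named genes, and chosen after their values were seen, the 5 genes at least 1.5-fold apart in the same direction in both were Efs and Klhl42, which were higher, and Angptl6, C1qtnf12 and Inava, which were lower. Other probe sets of C1qtnf12 gave 1.01, at least 2-fold higher, and 0.15 in the endothelial cells and 0.08 in McA-RH7777 cells, and another of Inava gave 0.50 in the endothelial cells. Independent lists of this size would share 2.74 higher and 1.75 lower genes. Another 6 genes were at least 1.5-fold apart in opposite directions, with Adck2, Ahi1 and Cacng2 higher in McA-RH7777 and lower in endothelial cells and Endov, Mapk7 and Slfn4 the reverse, where 2.39 and 2.01 would be shared. A dimmer probe set of Adck2 gave -0.21 in McA-RH7777 cells. Some of these folds are bounds with 1 signal under the floor: Efs in both cell types, Inava, Cacng2 and Slfn4 in the endothelial cells, and Mapk7 in McA-RH7777 cells.

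The size of folds depended on signal. In McA-RH7777 cells, 89, 45, 27 and 2 probe sets at least 2-fold apart lay in 4 equal bins of measured probe sets from lowest to highest signal, and the SD of log2 folds was 0.38 in the lowest bin and 0.16 in the highest. The endothelial counts were 192, 230, 23 and 5, with an SD of 0.45 in the lowest and 0.15 in the highest bin. Where a gene with a probe set at least 2-fold apart had another measured probe set, the brightest other one was itself at least 2-fold apart in that direction in 0 of 88 higher and 0 of 13 lower cases in McA-RH7777 cells. It was so in 0 of 169 higher and 0 of 93 lower cases in the endothelial cells. Dimmer probe sets did so for a few genes. Any other measured probe set was at least 2-fold apart in the same direction in 11 of the 88 higher cases in McA-RH7777 cells, from 5 genes (Aff4, Dhx36, Eif4g1, Tpr and Zfp91), and in 2 of the 169 higher cases in the endothelial cells, both from Map3k12, but in none of the lower cases. In the opposite direction there were 4 of the 169 higher and 4 of the 93 lower cases in the endothelial cells, from Lats2, Mrps5, Nisch and Zmym3, which each had probe sets at least 2-fold higher and lower, and 0 cases in McA-RH7777 cells. These genes were named after their values were seen, and their brightest other probe sets lay between -0.38 and 0.15. Medians of these other probe sets were -0.03 and 0.02 in McA-RH7777 cells and 0.00 and 0.02 in the endothelial cells.

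**Figure D3:**
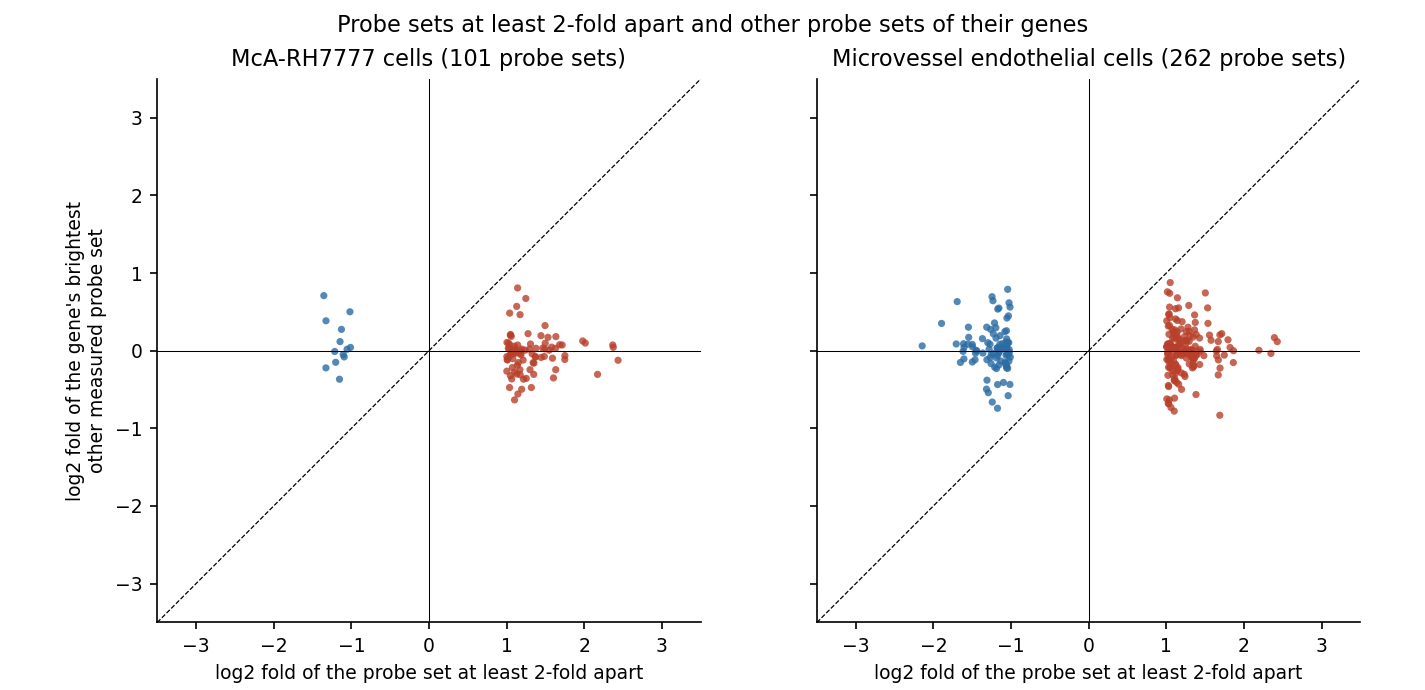
Log2 fold (HGFK1 over EGFP) of the brightest other measured probe set of a gene against that of its probe set at least 2-fold apart (red higher, blue lower), in McA-RH7777 cells (left) and microvessel endothelial cells (right). On the dashed line both probe sets would have the same fold; the points lie around 0 on the vertical axis instead, with medians of -0.03 and 0.02 (left, higher and lower) and 0.00 and 0.02 (right).

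Control transcripts added from outside the cells also differed between arrays. The bacterial poly-A controls, added before labelling, were 1.61-fold higher on the HGFK1 array of McA-RH7777 cells, with all 24 probe sets above 0, and 0.956-fold in the endothelial pair. Hybridisation controls were 1.08-fold and 1.28-fold higher with HGFK1 in the 2 pairs. The ratio of 3' to 5' signal of actin, a sign of RNA integrity, was 1.87 with HGFK1 and 1.78 with EGFP in McA-RH7777 cells and 1.13 and 1.17 in the endothelial cells, and that of GAPDH was 1.04 and 1.06, and 0.797 and 0.809.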

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

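The tests of the excess of higher probe sets were all chosen after the result was seen, and the values that drew attention here were not planned comparisons.

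The medians of the G1/S cyclins and E2F targets lay on opposite sides of 0 in the 2 cell types. The median log2 fold was 0.12 over 18 measured members in McA-RH7777 cells and -0.10 over 22 in the endothelial cells, a difference of 0.21. The measured members were not the same set on the 2 arrays, and 9 of the 22 endothelial members were above 0. The difference was not tested, since each side is 1 pair of arrays, and each list lay inside the range of random lists under 1 alternative, in McA-RH7777 cells with a floor at the 75th percentile (96.5th percentile) and in the endothelial cells with averaged probe sets (8.2nd percentile). Hybridisation controls, which come from outside the cells and enter no comparison, were 1.28-fold higher on the HGFK1 array of the endothelial cells.

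Poly-A controls, which also come from outside the cells, were 1.61-fold higher on the HGFK1 array of McA-RH7777 cells, the pair in which 137 probe sets were at least 2-fold higher and 26 lower. The size of that excess depended on the floor. Higher probe sets made up 84.0% of those at least 2-fold apart, but 67.0% with a floor at the 25th percentile and 62.1% with no floor. The share was 90.5% with a floor at the 75th percentile and 91.7% with a pseudocount. By brightest probe set, 30 genes were higher and 14 lower. Scaling is argued against as the cause of the excess, since 80.8% of probe sets at least 2-fold apart were still higher after quantile normalization. A symmetric spread of low signals would give similar numbers higher and lower. Of probe sets at least 2-fold apart, 72 were higher and 17 lower at mean signals from 69.8 to 165. From 165 to 451, the median signal of measured probe sets, 38 were higher and 7 lower. These counts argue against a symmetric spread, although some genes are counted through several probe sets. Above that median 27 of 29, 93.1%, were higher (exact binomial 95% interval 77.2 to 99.2%, over probe sets that are not independent). Those 29 do not bear on the low signals. Probe sets designed on expressed sequence tags may contribute: 6.67% of 105 higher probe sets with an accession were named through a RefSeq mRNA, within the 4.76 to 16.2% of random sets matched on signal, which leaves this open. A response to HGFK1, and a difference in the amount or labelling of RNA on 1 array, both stay open and untested.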

How the results depend on the processing

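All alternatives were fixed before the data were examined except matching lists without synonyms, which was chosen after seeing the data and left 6 and 4 lists apart, as before. No paired analysis was possible because each group was 1 array.

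Median centring, quantile normalization and loess kept all 4 counts of probe sets within 1.5 times, as a pseudocount did for the endothelial counts, and the other settings moved them. In McA-RH7777 cells, higher and lower probe sets numbered 1330 and 654 with a floor at the 25th percentile, 19 and 2 at the 75th, 4205 and 2571 with no floor, 66 and 6 with a pseudocount, 19 and 0 at 3-fold, 549 and 286 at 1.5-fold, and 30 and 14 as genes. In the endothelial cells they numbered 3444 and 2857 with a floor at the 25th percentile, 6 and 4 at the 75th, 6585 and 6074 with no floor, 25 and 15 at 3-fold, 1428 and 941 at 1.5-fold, and 79 and 59 as genes. Background levels and detection calls were not used, so how far these signals lay above background was not measured. Genes at least 2-fold apart in both cell types numbered 32 (higher in both), 16 (lower in both), 39 (higher in McA-RH7777 cells, lower in endothelial cells) and 21 (the reverse) with a floor at the 25th percentile, where independent lists would share 13.0, 7.11, 12.3 and 7.49. With no floor they numbered 193, 107, 187 and 100, against 77.2, 46.1, 76.1 and 46.8, so that same and opposite directions both lay above these values. The correlation between cell types stayed between -0.02 and 0.01.

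Endothelial lists standing apart numbered 2 after quantile normalization and 2 with a floor at the 25th percentile. Hepatocyte markers stood apart under all 10 alternatives (medians 0.08 to 0.15). After quantile normalization the ribosomal protein medians reversed to -0.0135 in McA-RH7777 and -0.00902 in endothelial cells, and NRF2 targets in endothelial cells had a median of 0.00251, inside the range of random lists. NRF2 targets also lay inside it with loess (0.0430), a floor at the 25th percentile (0.0573) and a pseudocount (0.0498). HGF and Met signalling in endothelial cells lay inside with a floor at the 25th percentile (0.0963), no floor (0.0963), averaged probe sets (0.127) and without shared probe sets (0.0832). Averaged probe sets also brought inside the endothelial G1/S genes (-0.0461) and, in McA-RH7777 cells, growth arrest genes (0.0570) and the unfolded protein response (-0.0208). In McA-RH7777 cells G1/S genes lay inside with a floor at the 75th percentile (0.0858), growth arrest genes with a floor at the 25th percentile (0.0992), no floor (0.0928) and a pseudocount (0.0900), and TGF-beta targets with no floor (-0.0939) and a pseudocount (-0.0514). The cause of these shifts was not tested. Of named genes at least 2-fold apart, only Sesn2 reversed, as its other probe set became the brightest. It lay at 0.63 with a floor at the 25th percentile, 0.63 with no floor and 0.40 with a pseudocount. Such genes were the 8 highest and 8 lowest taken in each cell type and 3 list members in each. Of them, 22 fell under 2-fold with a pseudocount and 10 with averaged probe sets. With a floor at the 75th percentile 3 did, where fewer named genes were measured. Changes of sign were not counted for named genes under 2-fold. Averaging probe sets moved 27 of these by more than the SD of folds at similar signal.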

Other observations

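The tests of probe sets at least 2-fold apart and of ribosomal protein genes were all chosen after the result was seen.

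Some gene groups near the edge of the random lists have not been described. In McA-RH7777 cells hypoxia genes had a median log2 fold of -0.09 (4.06th percentile), with Car9 at 0.27 and P4ha2 at 0.27 as the members furthest from 0, and heat shock proteins had a median of -0.07 (4.43rd percentile), with the chaperone partners Chordc1 at -0.60 and Stip1 at -0.27. Heat shock proteins were similarly placed in the endothelial cells, at -0.05 (4.69th percentile), with Cryab at -0.30, another probe set of it at 0.11, and Hspb8 at least 1.55-fold higher. Integrins and adhesion genes had a median of 0.08 (96.5th percentile) in McA-RH7777 cells, from Pxn at -0.40 to Itga1, at least 2.02-fold higher. NRF2 targets, at 0.08 there, had Abcc1 at -0.44 and Gstm2 at -0.33 as the members furthest from 0, and mitosis genes ran from Ccnf at -0.47 to Plk1 at 0.41. Further inside the range, acute-phase genes had a median of 0.09 (93.0th percentile) in McA-RH7777 cells, with Serpina3n at 0.42 and Crp at 0.30. In the endothelial cells the phosphoinositide 3-kinase, AKT and mTOR list had a median of 0.09 (96.5th percentile), with Pik3cb at -0.45 against Pik3r1 at 0.94. Interferon-stimulated genes there had a median of 0.06 (92.8th percentile), from Iigp1 at -0.77 to Gbp3 at 0.68. TGF-beta targets, lower in McA-RH7777 cells, had a median of 0.06 (88.3rd percentile) in the endothelial cells, with the inhibitor Smad7 at 0.98 and Tgfb3 at 0.64.

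Among brightly measured genes, a few probe sets stood far from the other probe sets of their gene; these genes were chosen after their values were seen. In the endothelial cells a probe set of Nme1, a nucleoside diphosphate kinase, was at -2.14 and its brightest other probe set at 0.06. Probe sets of Tax1bp1, Rab2a and Atp5a1 were at 1.54, 1.43 and 1.25, and the brightest others at 0.35, 0.16 and 0.05. In McA-RH7777 cells the translation factor Eif3c was at 1.24 and 0.01, the exonuclease Xrn2 at 1.15 and -0.15, and the ubiquitin-conjugating enzyme Ube2d2 at -1.13 and 0.27.

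The folds of probe sets at least 2-fold apart were weighed against the rest of their genes. A change in the level of the whole gene is argued against only for those whose gene had another such probe set, as a set: other probe sets of the same genes with both signals above the floor had a median log2 fold, signed in the direction of the first, of -0.0345 in McA-RH7777 cells (95% bootstrap interval -0.08 to 0.01, SD 0.24, 97 pairs) and of -0.0012 in the endothelial cells (-0.03 to 0.03, SD 0.27, 244 pairs). Counting each gene once per direction gave -0.03 (-0.08 to 0.01, 91 genes) and 0.00 (-0.03 to 0.03, 243 genes), although 5 genes in McA-RH7777 cells and 1 in the endothelial cells had more than 1 probe set at least 2-fold apart in the same direction. The wider spread of low signals may account for many, since 82.2% in McA-RH7777 cells and 93.8% in the endothelial cells lay below the median signal of measured probe sets. The other measured probe set was the brighter one in 77 of 88 higher and 8 of 13 lower cases in McA-RH7777 cells. In the endothelial cells it was so in 144 of 169 and 80 of 93. Genes named by their brightest probe set are therefore little covered. In McA-RH7777 cells 11 of the 88 higher cases had another probe set at least 2-fold higher, and 0 had one at least 2-fold lower. Single genes, those with 1 probe set and changes in 1 transcript form stay open, and a response to HGFK1 was not separately tested.

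Ribosomal protein genes were higher with HGFK1 in both cell types, and their transcripts are among the brightest. A stretch of the brightest signals on 1 array of each pair could account for this. Against lists drawn from the 30 genes nearest in signal to each member, the ribosomal medians lay at the 94.1st percentile in McA-RH7777 cells and the 58.4th in the endothelial cells, inside the middle 95%, and quantile normalization removed the shift. Removal of a loess curve lowered the medians to 0.07 and 0.10, at the 92.2nd and 48.4th percentile of lists drawn in the same way, although still at the 99.8th and 100th of lists from the wider signal bins. A response of ribosomal protein genes to HGFK1 stays open and untested.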
